A study of Mus musculus with 10 samples.

How the data were processed

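The data were expression values from 10 Affymetrix arrays, each hybridised with biotin-labelled RNA from differentiating mouse embryonic stem cells of the C57BL/6 strain. Total RNA was extracted on RNeasy columns with DNase digestion, its quality was read on a Bioanalyzer, and it was labelled with the One-Cycle kit, per the labels' protocols. The authors deposited log2 expression values for 45101 probe sets, made with RMA per the submitters' processing notes and with Bioconductor per the labels. RMA corrects background, quantile-normalises the arrays and summarises the probes of each probe set. Its version, and whether all 10 arrays were normalised together, are not given in the sources used here. Because quantile normalisation gives all arrays about the same distribution, a shift of most genes in one direction would be removed, and differences are relative to the other genes of the same array. Values near the bottom of the scale are compressed, so that differences of dim genes are understated.

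Probe sets were named from the platform annotation, whose symbols already matched the current ones (0 were changed through Entrez identifiers against the gene table of assembly GRCm38.p6). Of the 45101 probe sets, 34945 had 1 gene symbol, 932 had several, 9160 had none and 64 were control probe sets. The 34945 represented 18193 genes. Each gene took the probe set with the highest mean over the 10 arrays, and no gene was filtered out. Of the named genes with several probe sets that passed, 29 of 55 for DCI, 27 of 58 from day 17 to day 24 and 44 of 74 from day 8 to day 17 had a probe set with less than 0.5 times the change or with the opposite sign. No genome build is named in the sources used here, so no coordinates are given. Of 569 genes on the fixed lists, 537 were measured by a probe set of 1 symbol.

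Arrays fell into 10 groups of 1 array each by day of differentiation (8, 17 or 24) and treatment. With no replicate arrays, differences were tested with an additive linear model in limma 3.58.1 (R 4.3.3), with terms for day, KGF and DCI over all 10 arrays and 5 residual degrees of freedom. The spread in that model holds array noise together with any departure from additive effects, and p-values measure only that spread. The KGF by DCI, DCI by day and KGF by day interactions were each added to the model of the 8 arrays of days 17 and 24, leaving 3 residual degrees of freedom. Variances were moderated with eBayes with a mean trend, p-values were adjusted by Benjamini-Hochberg over the 18193 genes, and a gene passed at an adjusted p under 0.05. Errors are standard errors of the moderated fit. Since the number of arrays limits the precision, the median standard error of a DCI difference was 0.10 on the log2 scale, and that of a KGF by DCI interaction 0.20.

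Before the data were examined, 32 gene lists covering cell types, pathways and control genes were fixed, together with the rule for named genes. The rule took the 10 largest rises and 10 largest falls per main contrast (5 each way per interaction) among genes past the threshold that moved the same way in every matched pair of arrays and reached the median of all values (log2 6.67) in a compared condition. It left out symbols that are clone or accession names, and added a fixed set of lung, endoderm and treatment-response genes and up to 4 members of each list with the largest differences. Lists were tested with limma's camera at its preset correlation of 0.01, with an estimated correlation, and with fry, and adjusted over the 32 lists of a contrast. For the cultures with both treatments against the control of the same day, which are single arrays, list medians were placed among 10000 random lists of the same size matched on mean level in 20 bins. That placement describes these arrays and is no test.

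The fits were tested on simulated data with 200 changed genes among 18193. For DCI, a log2 change of 1 was recovered for 92.5% of genes and a change of 0.5 for 49.0%. For KGF the shares were 93.0% and 56.0%. These simulations gave every array with a treatment the same change, day 8 included for KGF, on independent noise. Their shares do not apply to an effect that differs by day. For the KGF by DCI interaction, a log2 change of 1 was recovered for 15.0% and a change of 2 for 90.0%. Alternatives were variance estimates without a trend or with a robust prior, a filter removing the lowest 40% of genes, the mean of a gene's probe sets, every probe set by itself, a second quantile normalisation, a 2-fold size in addition, an adjusted p under 0.10, models on subsets of arrays, matched pairs, and leaving out each array in turn. A covariate for the 3′ to 5′ signal difference of a spike-in control was added after the data were seen. For named genes and lists, direction was compared only where a result had passed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.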

Results

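Gene expression was measured in mouse embryonic stem cells after 8, 17 or 24 days of differentiation. The cultures had received keratinocyte growth factor (KGF, also called FGF7, an epithelial mitogen), DCI, both, or neither. DCI is taken here as the treatment with dexamethasone and raised cAMP that the series title names. The title places the question: whether the treatments together support differentiation toward alveolar type II cells, the surfactant-producing cells of the lung. There were 2 arrays at day 8 (control and KGF) and 4 each at days 17 and 24 (control, KGF, DCI, and KGF with DCI), with 1 array per condition and no replicates. Day accounted for most of the variation. The first principal component held 69.1% of the variance and placed the day 8 arrays apart from the rest, and the second held 14.5%. The day 8 control array stood apart in its control signals. Its 3′ minus 5′ difference was 1.05 for Actb against 0.46 to 0.62 on the other arrays, and 5.34 for the dap spike-in, above every other array (1.91 on the day 8 KGF array).

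In the cultures with both treatments, the surfactant genes, Napsa, Aqp5, Ager and Scgb1a1 read higher than in the control of the same day, while some other lung markers did not, as single-array values without a replicate check. Sftpc, which encodes surfactant protein C, read log2 4.38 in the day 17 control, 5.46 with KGF, 5.40 with DCI and 8.03 with both. At day 24 the values were 5.29, 6.89, 6.05 and 7.34, and at day 8 they were 4.34 in the control and 4.13 with KGF. Sftpa1, for surfactant protein A, lay between 3.97 and 4.28 on the arrays without the combination, and at 5.72 at day 17 and 5.19 at day 24 with both treatments. Sftpb was higher with both treatments by 0.78 at day 17 and 0.41 at day 24, Sftpd by 1.15 and 0.71, and Napsa by 0.94 and 1.22. These differences include the effects of each treatment alone. Napsa read 6.36 with DCI alone and 6.63 with both at day 17, and 7.55 and 7.64 at day 24. Sftpd read 7.87 with KGF alone and 8.41 with both at day 17. At day 24 Sftpd read 11.19 with KGF alone, above its value with both. At day 8, without DCI, Sftpb read 5.096 in the control and 5.698 with KGF, and Sftpd 5.548 and 4.697. Scgb1a1, the club cell secretory protein, rose with DCI in the additive fit by 2.40 ± 0.28 (SE; adjusted p = 0.000262). Nkx2-1, the lung and thyroid lineage factor, stayed between 4.45 and 5.00 on all 10 arrays, in the lower part of the scale. With both treatments Abca3, the surfactant lipid transporter, differed from the control by 0.07 at day 17 and -0.04 at day 24, and Etv5 by -0.10 and -0.58. Of the type I markers, Aqp5 was higher by 2.11 and 2.52 and Ager by 0.75 and 0.58, while Hopx differed by 0.66 and -0.10 and Pdpn by 0.18 and 0.02. Aqp5 read 7.27 with DCI alone and 8.08 with both at day 17, and 9.92 and 10.12 at day 24. Foxj1, of ciliated cells, differed by 0.89 and 0.10. In the additive fit Sftpc did not pass for DCI (1.20 ± 0.38, adjusted p = 0.0563) or for KGF (1.28 ± 0.34, adjusted p = 0.353). The other Sftpc probe set gave -0.09 for DCI and 0.10 for KGF.

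**Figure D1:**
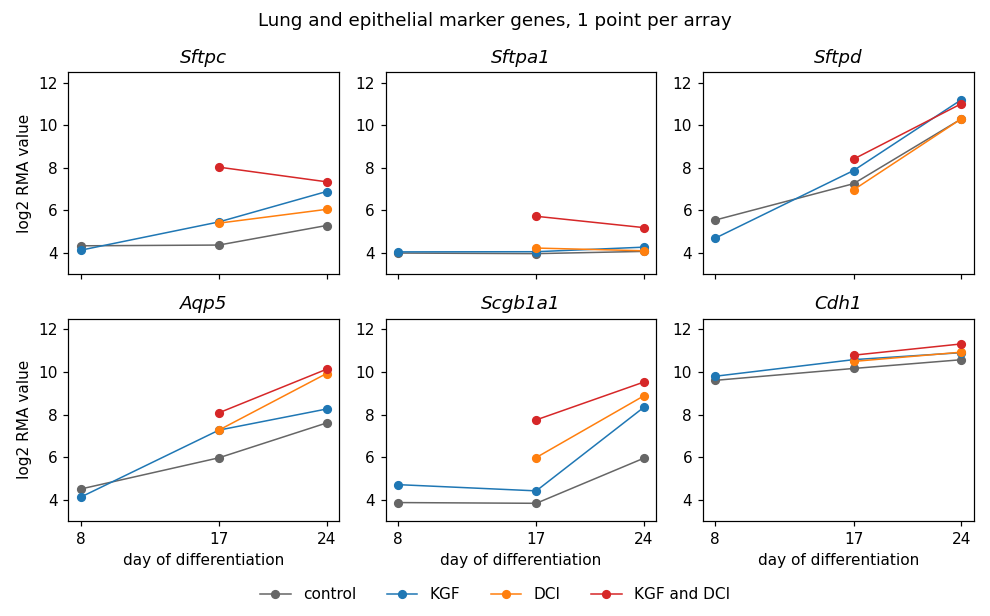
Log2 RMA values of 6 marker genes (y axes) against day of differentiation (x axes), with 1 point per array, coloured by treatment. With both treatments Sftpc read 8.03 at day 17 against 4.38 in the control, and Sftpa1 read 5.72 against 3.97.

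Over all genes, 533 differed at least 2-fold between both treatments and control at day 17 and 865 at day 24. Of these, 331 did so in the same direction on both days (158 higher, 173 lower). The highest were Bpifa1, an airway secretory protein (4.41 at day 17 and 5.28 at day 24 on the log2 scale), the trefoil peptide Tff1 (4.02 and 4.34), the gastric mucosal protein Gkn1 (3.71 and 4.91), Scgb1a1 (3.91 and 3.57), the airway mucin Muc5b (3.42 and 4.06) and Reg3g (3.81 and 3.42). Agr2 and Clca1, genes of mucus-producing cells, were higher by 3.03 and 2.93 at day 17. The lowest included the chemokine Ccl12 (-3.47 and -6.24), Cx3cr1 (-3.85 and -3.56) and Cd48 (-3.28 and -3.47). The airway epithelium list had a median difference of 0.87 at day 17 and 0.47 at day 24, and the general epithelium list 0.61 and 0.72, all at the 100th percentile of random lists. The alveolar type II list stood at 0.32 at day 17 (percentile 99.99) and at -0.04 at day 24 (percentile 39.0), and the type I list at 0.07 (percentile 79.8) and -0.04 (percentile 43.0). The macrophage list stood at -1.68 and -3.77, at percentile 0 on both days.

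DCI lowered macrophage genes and raised genes of glucocorticoid and cAMP responses and of intestinal and general epithelium. The smallest list result was adjusted p = 0.0747 with an estimated correlation. DCI changed 2793 of 18193 genes, 1322 higher and 1471 lower, and 432 of them by at least 2-fold. The largest fall was in Ccl12, a monocyte-attracting chemokine (-4.85 ± 0.36, 28.9-fold, adjusted p = 1.42e-05). Fcrls (-3.62 ± 0.11), Aif1 (-3.60 ± 0.35), Ly86 (-3.59 ± 0.25), the fractalkine receptor Cx3cr1 (-3.50 ± 0.19), Hpgds (-3.38 ± 0.14), Clec4a3 (-3.25 ± 0.28), Plek (-3.24 ± 0.23), the mannose receptor Mrc1 (-3.09 ± 0.27) and Mpeg1 (-3.06 ± 0.31) followed, each lower in 4 of 4 matched pairs. Of 18 measured macrophage genes, 16 fell and 1 rose, with 16 and 2 when adjusted over the list alone. The list median was -2.14 (camera adjusted p = 1.48e-15, or adjusted p = 0.179 with an estimated correlation). The gene that rose was Cd163, a scavenger receptor known to be induced by glucocorticoids (1.15, adjusted p = 0.000982). Among hematopoietic genes, Ptprc, the pan-leukocyte antigen CD45, fell by 2.74 and the myeloid factor Spi1 by 1.09. Other probe sets gave -0.27 for Ptprc, -1.34 for Cx3cr1 and, at the smallest, -0.71 for Plek. That list had 3 of 16 members lower and a median of -0.06, and its camera test did not pass (adjusted p = 0.0913).

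The glucocorticoid response list had 17 of 24 members higher with DCI (18 adjusted over the list alone, and 1 lower), with a median of 0.66 (camera adjusted p = 3e-13, or adjusted p = 0.0747 with an estimated correlation). Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor, rose by 1.75 ± 0.16, or 3.37-fold. Zbtb16 rose by 1.61 ± 0.11, Klf15 by 1.52 ± 0.14, Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, by 1.45 ± 0.09, and Per1 by 1.29 ± 0.08. The lowest of the other probe sets gave 0.05 for Fkbp5, 0.23 for Zbtb16 and 0.18 for Tsc22d3. Of 22 cAMP response genes, 12 rose and 3 fell (13 and 3 adjusted over the list alone), with a median of 0.57 (camera adjusted p = 1.23e-05, or adjusted p = 0.143 with an estimated correlation). The cAMP phosphodiesterase genes Pde7b, Pde4d and Pde4b rose by 1.92, 1.75 and 1.39, and Nr4a1 by 0.59. The lowest of their other probe sets gave 0.31 for Pde7b, 0.05 for Pde4d and -0.03 for Pde4b. Crem was at -0.09 ± 0.14 and did not pass, with 1 of its 4 probe sets on the other side of 0.

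Among epithelial genes, the largest rises with DCI were in Gkn1 (3.85 ± 0.45), Tff1 (3.75 ± 0.11, 13.5-fold), Gkn2 (3.41 ± 0.46), the intestinal stem cell marker Olfm4 (3.11 ± 0.19), the goblet cell peptide Spink4 (3.06 ± 0.07), Mptx1 (2.76 ± 0.32) and Muc5b (2.66 ± 0.34). The neutrophil-attracting chemokines Cxcl3 (3.52 ± 0.31) and Ppbp (3.18 ± 0.46) and the melanocortin receptor accessory protein Mrap (2.98 ± 0.20) also rose, with the other Mrap probe set at 0.02. Of 14 intestinal epithelium genes, 8 rose and none fell, before and after adjustment over the list alone, with a median of 0.71 (camera adjusted p = 2.44e-05, or adjusted p = 0.179 with an estimated correlation). They included the trefoil peptide Tff3 (2.53 ± 0.13) and the goblet cell mucin Muc2 (2.43 ± 0.19). Of 20 general epithelium genes, 11 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 2.42e-09, or adjusted p = 0.143 with an estimated correlation). E-cadherin, Cdh1, rose by 0.33 and Epcam by 0.56, while Cldn6 fell by 0.50. The airway list had 3 of 16 members higher (Muc5b, Scgb1a1 and Muc5ac) over all genes and over the list alone, and its camera test did not pass (adjusted p = 0.129).

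Alveolar genes went both ways with DCI. Of 21 type II genes, 2 rose and 5 fell (4 and 5 adjusted over the list alone), and the list's camera test did not pass (adjusted p = 0.671). Napsa, which encodes the aspartic protease that processes surfactant protein B, rose by 1.01 ± 0.10 and Muc1 by 1.04 ± 0.13. Lyz2, also abundant in macrophages, fell by 2.83 ± 0.38. Of 14 type I genes, 2 rose and 2 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.989), with the water channel gene Aqp5 higher by 1.57 ± 0.26. Akap5 fell by 0.87, with another probe set at -0.13, and the other Napsa probe set stood at 0.31. Smooth muscle genes fell in 5 of 12 cases (7 adjusted over the list alone; median -0.26; camera adjusted p = 0.000327, or adjusted p = 0.138 with an estimated correlation), among them Tagln by 0.71 and Acta2 by 0.54 (another Acta2 probe set at -0.21). Of 19 hypoxia and glycolysis genes 8 rose (10, and 1 lower, adjusted over the list alone), with a median of 0.28 (camera adjusted p = 8.65e-05, or adjusted p = 0.206 with an estimated correlation), and Vegfa rose by 0.53. Of 20 sterol and fatty acid synthesis genes 6 rose (7, and 1 lower, adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.000509, or adjusted p = 0.206 with an estimated correlation). Of the stress list's 17 genes 7 rose (8, and 2 lower, adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.0363, or adjusted p = 0.547 with an estimated correlation). The 10 housekeeping genes had a median of -0.06. The DCI count fell to 1638 without the day 24 control array and to 1821 without the day 24 DCI array.

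KGF raised 1 gene past the threshold over all 10 arrays: Reg3g, which encodes an antibacterial lectin of mucosal epithelia (1.40 ± 0.14, 2.63-fold, adjusted p = 0.0302, higher in 5 of 5 pairs). At an unadjusted p under 0.05 there were 1466 genes, and 13 passed at an adjusted p under 0.10, 12 of them higher. Bpifa1 was 3.01 higher and Cdh1 0.32, each with an adjusted p of 0.0842. For KGF 15 of 32 lists passed with camera at its preset correlation, 1 with fry and 0 with an estimated correlation. Not all of the 15 are named here, and KGF results of the alveolar lists are not given. Of 20 general epithelium genes none passed over all genes, and 18 were higher when adjusted over the list alone. The list median was 0.32 (camera adjusted p = 6.53e-25, or adjusted p = 0.0674 with an estimated correlation). Of 16 airway genes none passed over all genes, and 11 were higher when adjusted over the list alone, with a median of 0.53 (camera adjusted p = 4.67e-12, or adjusted p = 0.21 with an estimated correlation). Skeletal muscle genes had a median of 0.65, with 5 of 16 higher adjusted over the list alone and none over all genes (camera adjusted p = 4.67e-12, or adjusted p = 0.221 with an estimated correlation). Their median level was 7.31 in the day 17 control against 8.87 with KGF, and 9.26 against 9.40 at day 24. Intestinal genes had a median of -0.33, with 3 of 14 lower adjusted over the list alone and none over all genes (camera adjusted p = 7.71e-06, or adjusted p = 0.21 with an estimated correlation). The FGF receptor feedback list, genes known to be induced by FGF signalling, had a median of 0.07 and no member past either adjustment (camera adjusted p = 0.00978, or adjusted p = 0.329 with an estimated correlation).

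On the 8 arrays of days 17 and 24 alone, 65 genes passed the test for KGF, 64 of them higher. The same fit results when either day 8 array is left out. The genes named here were chosen after their values were seen. Bpifa1 rose by 3.68 ± 0.21 (12.8-fold, adjusted p = 0.000287). Secreted products of airway and lung epithelium were among the 64, with Wfdc18 (1.85 ± 0.095), the lung chemokine Cxcl15 (1.74 ± 0.22), Cxcl17 (1.49 ± 0.11), Wfdc2 (1.05 ± 0.09), Sftpd, which encodes surfactant protein D (0.92 ± 0.12), and the membrane mucin Muc4 (0.90 ± 0.13). So were genes of the ciliary axoneme and its assembly, with Dynlrb2 (1.83 ± 0.25), Pifo (1.40 ± 0.19), Nme5 (1.01 ± 0.16), Rsph4a (0.87 ± 0.09) and Rsph1 (0.85 ± 0.13). The epithelial transcription factors Ehf, Grhl2, Klf5 and Foxa1 rose by 0.69, 0.57, 0.55 and 0.53. Over all 10 arrays, 2 of the 4 Grhl2 probe sets lay below 0. The apelin receptor gene Aplnr fell by 0.60 ± 0.08. The count of 1 on all arrays became 0 when any of the 4 day 17 arrays, the day 24 control or the day 24 DCI array was left out, and 2 without the day 24 KGF array or the day 24 array with both treatments. It was also 0 without a mean trend in the variances and with the mean of a gene's probe sets, and a robust prior called 1 gene other than Reg3g.

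**Figure D2:**
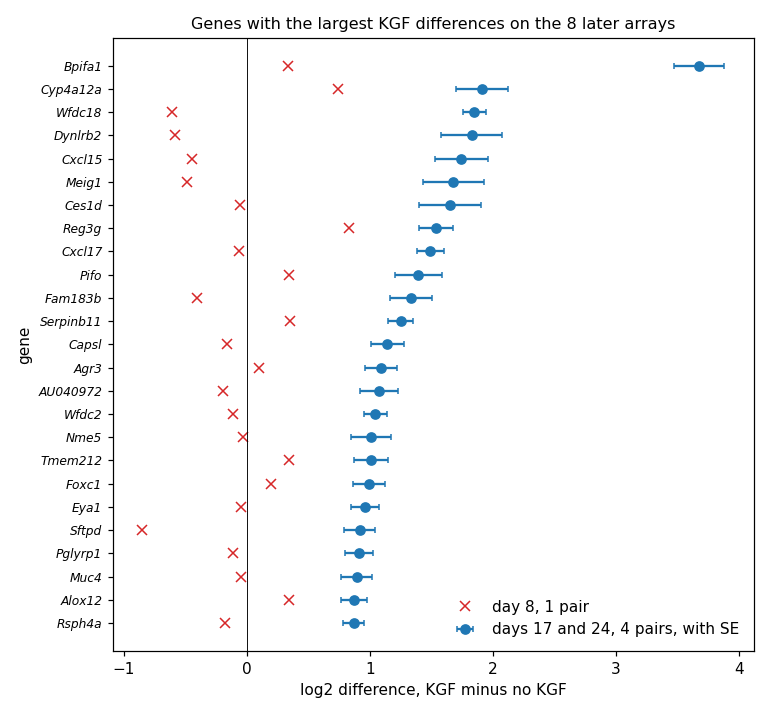
Log2 difference, KGF minus no KGF (x axis), for the 25 genes with the largest differences among the 65 called on the 8 later arrays (y axis). Circles are the fit over 4 pairs with standard errors, and crosses the single day 8 pair; Bpifa1 stands at 3.68 on the later arrays and at 0.33 at day 8.

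No gene passed for the KGF by DCI interaction in limma, which asks whether the combination differs from the sum of the single treatments on the log2 scale. At an unadjusted p under 0.05 there were 267 genes, and the smallest adjusted p was 1.00. Sftpa1 had an interaction of 1.14 ± 0.28, Sftpb of 0.66 ± 0.25 and Sftpc of 0.62 ± 0.59, none past the threshold. The Sftpc value pools days of opposite sign. By the array values above, Sftpc with both treatments lay above the sum of the single effects at day 17 and below it at day 24. The alveolar type II list had a median interaction of 0.22 with no member past either adjustment (camera adjusted p = 0.000828, or adjusted p = 0.533 with an estimated correlation). Cardiac muscle genes had a median of -0.24 (camera adjusted p = 6.98e-06, or adjusted p = 0.52 with an estimated correlation) and interferon response genes -0.30 (camera adjusted p = 0.00157, or adjusted p = 0.52 with an estimated correlation), likewise with no member past either adjustment. The median 95% confidence interval of an interaction, not adjusted over the genes, spanned 0.46 to either side. In the simulated data a log2 interaction of 1 was recovered for 15.0% of genes and one of 0.5 for 0%. Most interactions of such sizes would thus have been missed with these arrays, and their absence is not shown.

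The effect of DCI differed between days 17 and 24 for 456 genes, 97 with a higher and 359 with a lower difference at day 24. With fry, 0 of 32 lists passed for this interaction, so the list calls below rest on camera at its preset correlation. Liver and yolk sac genes were higher with DCI at day 17 and not at day 24. The visceral endoderm and liver list had 14 of 19 members with a lower DCI difference at day 24 (17 adjusted over the list alone) and a median interaction of -1.21 (camera adjusted p = 2.45e-25, or adjusted p = 0.358 with an estimated correlation). Its median DCI difference was 1.06 at day 17, with 18 of 19 members above 0, and -0.26 at day 24. Apob, of the lipoprotein particle, went from 0.44 to -2.48, Cubn, an endocytic receptor of the yolk sac, from 1.38 to -1.37, and Apoa4 from 1.25 to -1.33. Macrophage genes were lower with DCI on both days, and 12 of 18 more so at day 24 (15 adjusted over the list alone, and 1 the other way). The list median interaction was -1.36 (camera adjusted p = 4.88e-16, or adjusted p = 0.358 with an estimated correlation), from -1.66 at day 17 to -3.10 at day 24. Of 16 endothelial genes, 6 had a lower difference at day 24 (10 adjusted over the list alone; median -0.84; camera adjusted p = 4.8e-10, or adjusted p = 0.358 with an estimated correlation), including Pecam1 (-1.63 ± 0.31), Icam2 (-1.65 ± 0.20) and VE-cadherin, Cdh5 (-1.57 ± 0.23).

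Among single genes with opposite or unequal DCI differences, the carbonic anhydrase gene Car4 went from -0.47 at day 17 to -3.67 at day 24 (interaction -3.20 ± 0.19, adjusted p = 0.000129). Higher differences at day 24 were led by Pgc, which encodes progastricsin (0.21 and 2.94), Gkn3 (0.90 and 3.17) and the goblet cell lectin Zg16 (1.43 and 3.70). For Gkn1, Gkn2 and Tff1 the interaction did not pass (adjusted p = 0.75, 0.91 and 0.96). Fam3b (interaction 2.12 ± 0.23) and Ctla2a (1.89 ± 0.15) went the same way, and Ppbp the other (-2.63 ± 0.40). The dap spike-in moved with this contrast. Its 3′ minus 5′ difference was higher on the DCI arrays by 0.98 at day 17 and by -0.16 at day 24, while that of Actb was higher by 0.12 and 0.06. The interaction count fell to 170 without the day 17 DCI array, 143 without the day 17 array with both treatments, 172 without the day 24 KGF array and 181 without the day 24 array with both. It was 138 without a mean trend in the variances and 223 with the mean of a gene's probe sets. The probe sets of each gene were not compared with one another for this contrast. For DCI over both days, the other Cdh5 probe set gave -0.08 against -0.705 for the one used.

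**Figure D3:**
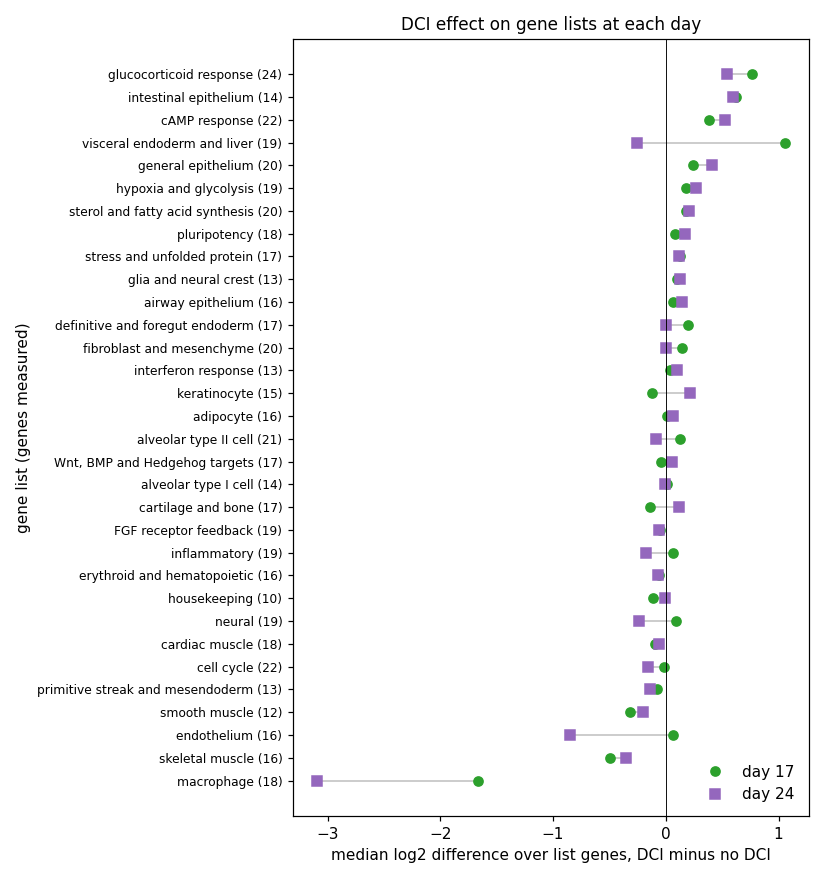
Median log2 difference between arrays with and without DCI (x axis) for each of 32 gene lists (y axis, genes measured in brackets). Circles are day 17 and squares day 24, each the mean of 2 pairs of arrays; the liver and yolk sac list moves from 1.06 to -0.26 and the macrophage list from -1.66 to -3.10.

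No gene passed for the KGF by day interaction in limma between days 17 and 24. There were 932 genes at an unadjusted p under 0.05, and the smallest adjusted p was 0.513. Skeletal muscle genes had a median of -0.88 with no member past either adjustment (camera adjusted p = 0.000143, or adjusted p = 0.66 with an estimated correlation). Neural genes had a median of -0.50 (camera adjusted p = 2.79e-06, or adjusted p = 0.66 with an estimated correlation), also with no member past.

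From day 8 to day 17, embryonic blood genes fell while macrophage, epithelial, liver and mesenchymal genes rose. The smallest list result was adjusted p = 0.0957 with an estimated correlation. In all 7713 genes changed, 3891 higher and 3822 lower, and 2355 by at least 2-fold. The largest rises were in the acute-phase gene Saa3 (8.78 ± 0.09), the gastric protease chymosin, Cym (8.72 ± 0.57), matrix Gla protein, Mgp (8.14 ± 0.13), the fatty acid carriers Fabp4 (8.12 ± 0.08) and Fabp1 (7.28 ± 0.44), the lysozymes Lyz1 (7.57 ± 0.37) and Lyz2 (7.54 ± 0.51), albumin, Alb (7.26 ± 0.16), Aldh1a1 (7.15 ± 0.18) and the club cell cytochrome Cyp2f2 (7.07 ± 0.45). The embryonic globins Hba-x, Hbb-y and Hbb-bh1 fell by 8.01, 8.01 and 7.72. Tdo2 (-5.34 ± 0.26), the red cell anion exchanger Slc4a1 (-5.09 ± 0.15), Nepn (-4.78 ± 0.35), Hemgn (-4.66 ± 0.13), Lhx2 (-4.26 ± 0.25), Hsd11b2 (-4.26 ± 0.16) and the hyaluronan synthase Has2 (-4.10 ± 0.18) also fell. The other probe sets reached as near to 0 as 0.17 for Fabp4, 0.51 for Lyz1, -1.21 for Tdo2 and -0.02 for Slc4a1. Of 18 macrophage genes 17 rose (the same number over the list alone), with a median of 5.32 (camera adjusted p = 2.37e-14, or adjusted p = 0.134 with an estimated correlation). Complement gene C1qa rose by 8.13 ± 0.52. Of 16 erythroid and hematopoietic genes 12 fell and 3 rose (the same over the list alone; median -3.03; camera adjusted p = 1.89e-05, or adjusted p = 0.0957 with an estimated correlation).

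Of 20 fibroblast genes 14 rose and 6 fell between days 8 and 17 (median 1.74; camera adjusted p = 2.93e-05, or adjusted p = 0.16 with an estimated correlation), and of 19 liver and yolk sac genes 12 rose and 2 fell (13 and 2 over the list alone; median 1.15; camera adjusted p = 0.000212, or adjusted p = 0.411 with an estimated correlation). General epithelium genes rose in 16 of 20 cases and fell in 4 (median 0.91, camera adjusted p = 2.93e-05, or adjusted p = 0.17 with an estimated correlation). Keratinocyte genes rose in 13 of 15 cases (median 1.11; camera adjusted p = 1.89e-05, or adjusted p = 0.111 with an estimated correlation), with Krt15 higher by 5.21 and Krt14 by 3.62 (0.48 at its lowest probe set). Of 21 alveolar type II genes 13 rose and 1 fell (median 0.74; camera adjusted p = 0.000332, or adjusted p = 0.25 with an estimated correlation). Sftpd rose by 2.49 ± 0.36, while Sftpc stood at 0.98 ± 0.50 and Sftpb at 0.11 ± 0.21 without passing. Neural genes rose in 14 of 19 cases (15 over the list alone; median 0.98; camera adjusted p = 4.13e-05, or adjusted p = 0.278 with an estimated correlation). The sterol and fatty acid synthesis list had 17 of 20 members lower (median -1.20; camera adjusted p = 4.88e-10, or adjusted p = 0.0957 with an estimated correlation), and the cell cycle list 21 of 22 (median -0.96; camera adjusted p = 1.99e-11, or adjusted p = 0.115 with an estimated correlation). Where no second count is given, the count adjusted over the list alone was the same. The day 8 control array, with its low 5′ control signals, is 1 of the 2 arrays on the early side; without it 5819 genes changed.

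From day 17 to day 24, cell cycle genes fell and genes of inflammation, hypoxia and skeletal muscle rose. The smallest list result was adjusted p = 0.0734 with an estimated correlation. The contrast changed 6778 genes, 2686 higher and 4092 lower, and 734 by at least 2-fold. Rises were led by Dmbt1, a mucosal scavenger protein (4.24 ± 0.21), the matrix metalloproteinase Mmp3 (3.96 ± 0.12), lipocalin 2, Lcn2 (3.49 ± 0.12), lactoferrin, Ltf (3.47 ± 0.21), Reg3g (3.43 ± 0.16), Wfdc18 (3.38 ± 0.35), the polymeric immunoglobulin receptor Pigr (3.32 ± 0.26), Reg1 (3.19 ± 0.30), Sftpd (3.07 ± 0.27) and Orm1 (3.06 ± 0.18). The largest falls were in Serpina6 (-3.34 ± 0.30), Dscc1 (-2.56 ± 0.16), sonic hedgehog, Shh (-2.21 ± 0.18), the urea cycle gene Cps1 (-2.15 ± 0.35), Aspm (-2.11 ± 0.08), Fras1 (-2.05 ± 0.14), Frem2 (-2.02 ± 0.10), Cenpf (-1.97 ± 0.12), Ttk (-1.91 ± 0.09) and Lrr1 (-1.91 ± 0.10). Of the 5 Aspm probe sets, 1 lay above 0, at 0.06. Other probe sets reached as near to 0 as -0.13 for Shh, -0.30 for Cenpf, -0.54 for Dscc1 and -0.60 for Ttk and Lrr1. Of 22 cell cycle genes all 22 fell, over all genes and over the list alone, with a median of -1.53 (camera adjusted p = 2.18e-21, or adjusted p = 0.0734 with an estimated correlation). Mki67, the proliferation marker, fell by 1.86 ± 0.08.

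Of 19 hypoxia and glycolysis genes 17 rose from day 17 to day 24 (median 0.53; camera adjusted p = 2.19e-11, or adjusted p = 0.0734 with an estimated correlation), among them Adm by 2.11 and Car9 by 1.89. Skeletal muscle genes rose in 15 of 16 cases (median 1.22; camera adjusted p = 6.37e-08, or adjusted p = 0.282 with an estimated correlation), with Acta1 higher by 2.45. Inflammatory genes rose in 12 of 19 cases (14 over the list alone; median 0.67; camera adjusted p = 2.42e-08, or adjusted p = 0.0734 with an estimated correlation) and interferon response genes in 10 of 13 (11 over the list alone; median 0.92; camera adjusted p = 1.72e-06, or adjusted p = 0.177 with an estimated correlation). General epithelium genes rose in 15 of 20 cases (15, and 1 lower, over the list alone; median 0.47; camera adjusted p = 1.18e-07, or adjusted p = 0.147 with an estimated correlation), with Cldn4 higher by 1.27. Adipocyte genes rose in 8 of 16 cases and fell in 1 (11 and 1 over the list alone; median 0.40; camera adjusted p = 0.000334, or adjusted p = 0.0734 with an estimated correlation). Of 21 alveolar type II genes 6 rose and 4 fell (6 and 5 over the list alone), and that list's camera test did not pass (adjusted p = 0.15). Where no second count is given, the count adjusted over the list alone was the same. Liver and yolk sac genes fell in 6 of 19 cases (median -0.36; camera adjusted p = 0.012, or adjusted p = 0.642 with an estimated correlation), with Alb lower by 1.46 ± 0.12. The list's median level went from 9.71 to 8.28 with DCI and from 9.84 to 8.31 with both treatments. In the control it went from 8.17 to 8.01, and with KGF alone from 7.91 to 8.19. With an estimated correlation no list passed in any of the 7 contrasts. Without single arrays the count of changed genes lay between 5298 and 6835.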

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

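Of the tests in this part, those of a shift of all genes, of macrophage number, of the macrophage list at day 24, of the day 8 noise, of the held-out pairs, of the control genes and of the list members were chosen after the result was seen. No condition had enough arrays for a search for single outlying samples.

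Genes whose DCI effect differed between days 17 and 24 by a test of the interaction numbered 456. The 8 later arrays gave 32 splits that could be fitted. The real one was the 1 split with as many genes, and the highest of the others gave 0. Those other splits carry the difference of the real grouping in their residual spread, so few calls were likely in advance. With 1 array per condition, the splits cannot exclude chance or a difference between single arrays. The single genes with the largest interactions were Car4 (-3.20), Apob (-2.92), Cubn (-2.75), Ppbp (-2.63) and Apoa4 (-2.58) among those lower at day 24, and Pgc (2.74), Gkn3 (2.28), Zg16 (2.28), Fam3b (2.12) and Ctla2a (1.89) among those higher. Probe sets with no gene name or several, which enter no comparison between genes, held 233 changed by DCI (125 higher, 108 lower) out of 10092.

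Liver and yolk sac genes were higher with DCI at day 17 (median 1.06) and not at day 24 (-0.26). A few members driving the list is argued against, since 14 of 19 members passed, all lower at day 24. A 3′ bias of the arrays cannot be told apart from this pattern: the 3′ minus 5′ differences of Actb and Gapdh changed between the days by at most 0.055, but that of the dap spike-in changed by -1.13, in step with the contrast. At day 8, where the control array had the stronger dap bias, the list differed from the KGF array by -0.04. A DCI-dependent gain of liver-type or yolk sac-type cells by day 17 may also lie behind it and stays untested.

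Macrophage genes were lower with DCI on both days. A shift of all genes from the normalization is argued against by the list's median lying -2.07 from that of the housekeeping list, with quartiles of -2.94 and -1.78 against -0.21 and 0.05, since a common shift leaves such a gap at 0. Loss of 5′ signal on the DCI arrays is argued against by the larger fall at day 24 (-3.10, quartiles -3.70 and -2.08), where the dap 3′ minus 5′ difference was lower on the DCI arrays, while the list median of -2.14 with that difference as a covariate adds little, since the covariate mostly sets the day 8 control array apart. Fewer macrophages in the DCI cultures may explain the pattern, as 16 of 18 members fell, but lower expression within the cells predicts the same, and Cd163 rose. In the 34 splits that could be fitted, 1 split, the real one, gave as many as the 2793 genes changed by DCI, and the highest of the others gave 2. These splits have the same limit as those for the DCI by day genes.

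For KGF, 65 genes passed on the 8 later arrays and 1 when day 8 was included. Noise from the day 8 control array around an unchanged effect is argued against by genes picked on 3 later pairs: their upper quartile at day 8 was at most 0.25, below the lower quartile of the held-out later pair in each of the 4 runs (at least 0.32). The airway list median was 4.34 and 4.52 on the day 8 arrays and 5.53 to 7.81 later. Differences of dim genes are understated, so the quartiles do not separate a smaller effect from low levels at day 8. A smaller KGF effect at day 8 may explain it: the 65 genes had a median of -0.053 at day 8 in their called direction, with 28 of 65 in that direction. The genes picked on 3 later pairs had a median of 0.52 to 0.90 in the pair held out and of -0.069 at day 8 over the 4 runs. With 1 pair at day 8, a shift of these genes on a single array stays open, untested.

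For KGF on all 10 arrays, 17 of 100 splits drawn gave at least the 1 gene, so chance could not be excluded. The highest other split gave 82 genes. It grouped the day 8 arrays, the day 17 arrays without DCI and the day 24 array with both treatments. Among the later arrays it differs from the DCI by day contrast only in the day 24 DCI array. What lies behind its count was not tested further. On the 8 later arrays, 2 of 33 splits gave as many as the 65 genes. The other of them, with 144, parts the arrays by day and DCI together. That is the DCI by day contrast and no random draw, so the count of 2 decides nothing about chance. With 1 array per condition, chance could not be excluded there either. For the days 17 and 24, 1 of 34 splits, the real one, gave as many as 6778 genes and the highest other gave 0. The other splits mix the 2 days and carry the day difference as residual spread, so few calls were likely in advance. They therefore do not exclude chance. For the KGF by DCI and KGF by day interactions, with 0 genes each, the 32 splits give as many by definition, which says nothing about chance, and the highest other, with 456, was again the DCI by day contrast.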

How the results depend on the processing

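The spike-in covariate was chosen after the data were seen, and with its highest value on the day 8 control array it mostly sets that array apart. The count of genes changed by DCI lay between 1638 and 2834 when single arrays were left out, was 432 with a 2-fold size in addition, and stayed within 1.5 times of 2793 under the other settings. From day 17 to day 24 the count was 734 with a 2-fold size and 11974 when every probe set was tested by itself, and 5298 to 6835 without single arrays. From day 8 to day 17 it was 2355 and 14255 under those settings, and 5819 to 7696 without single arrays. The larger counts come from more probe sets tested and the smaller from the added criterion. The KGF count of 1 became 0 without a mean trend and with the mean of a gene's probe sets, 2 without the lowest 40% of genes, 13 at an adjusted p under 0.10, 65 on the 8 arrays of days 17 and 24, 10 with matched pairs, 69 with the spike-in covariate, and 0 to 65 without single arrays. The DCI by day count of 456 became 138 without a mean trend, 223 with the mean of a gene's probe sets, 764 with every probe set, 230 with a 2-fold size, 814 at an adjusted p under 0.10, and 143 to 454 without single arrays. Apart from the added criteria and the tested number of probe sets, the cause was not tested. The KGF by DCI and KGF by day interactions had 0 genes in limma under every setting run (267 and 932 at an unadjusted p under 0.05). The count of genes at least 2-fold apart between both treatments and control in the same direction on both days was 331, 321 after a second quantile normalisation and 281 with the mean of a gene's probe sets.

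No named gene that passed changed direction in the settings compared, which left out the test of every probe set by itself. For the largest rises and falls this was likely in advance, since the naming rule required the same sign in every matched pair. The pair counts given with such genes follow from that rule. No list that passed in both settings changed direction, and with the estimated correlation none could, since no list passed. For DCI, 4 of 55 passing named genes with several probe sets had one of opposite sign. The counts were 12 of 58 from day 17 to day 24 and 9 of 74 from day 8 to day 17. For DCI, leaving out each array in turn kept the side of the threshold in 1529 of 1680 cases over the named genes, with 117 no longer past it and 34 newly past it. For the gene lists, the estimated correlation ended every preset call, 10 for DCI and 15 for KGF, and fry ended 1 and 14 of these. For the interactions, the estimated correlation and fry each ended every preset call. These were 9 for DCI by day, 7 for KGF by DCI and 7 for KGF by day. The mean of a gene's probe sets ended 6 of the 9 DCI by day calls. No paired analysis by replicate number was possible because the labels give none. Arrays without replicates limit all of these results, and dim genes are limited further by signal near background.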

Other observations

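The tests of both hypothesis lists without their shared genes were chosen after the results were seen. Both hypotheses came from the same data, and single genes named here were chosen after their values were seen.

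Nanog read log2 5.70 in the day 17 control, 6.55 with KGF, 5.54 with DCI and 6.85 with both, and at day 24 it read 4.59, 4.48, 6.12 and 5.07. Pou5f1, which encodes OCT4, read 5.34, 6.00, 5.34 and 6.24 at day 17 and 3.93, 3.97, 5.39 and 4.79 at day 24. In the KGF by day interaction the list of 18 genes had a median of -0.41 with no member past the threshold (camera adjusted p = 9.64e-08, or adjusted p = 0.603 with an estimated correlation). The culture with both treatments at day 17 had a list median of 0.72 over the control, at the 100th percentile of random lists, and 0.06 at day 24.

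Muscle and mesenchymal genes differed by contrast. Cardiac muscle genes had a median of 0.17 with KGF and no member past either adjustment (camera adjusted p = 8.12e-06, or adjusted p = 0.221 with an estimated correlation). From day 17 to day 24, 6 of 18 cardiac genes fell and 1 rose, among them Myl2 by 0.74 and Mybpc3 by 0.71, and the list's camera test did not pass (adjusted p = 0.914). The list median was 0.11, while its mean of -0.07 and its camera test were negative. Of 12 smooth muscle genes 7 rose over the same days (median 0.26; camera adjusted p = 0.000702, or adjusted p = 0.0734 with an estimated correlation). The astrocyte water channel gene Aqp4 rose by 2.64 ± 0.23 from day 17 to day 24. Adiponectin, Adipoq, read 6.55 in the day 24 control, 2.99 with KGF, 2.91 with DCI and 4.37 with both, against 2.45 to 2.82 at day 17. Of 17 targets of Wnt, BMP and Hedgehog signalling 10 fell and 1 rose from day 17 to day 24 (10 and 2 over the list alone; median -0.37; camera adjusted p = 0.0375, or adjusted p = 0.313 with an estimated correlation), with Bambi lower by 1.10 and Lef1 by 0.82.

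With DCI, camera tests did not pass for the lists of definitive and foregut endoderm (adjusted p = 0.176), keratinocyte (0.605), pluripotency (0.0927), primitive streak (0.176), cardiac muscle (0.467), skeletal muscle (0.0949), fibroblast (0.146), cartilage and bone (0.808), adipocyte (0.282), neural (0.66), glia and neural crest (0.244), endothelium (0.158), FGF receptor feedback (0.66), inflammatory (0.752), interferon response (0.368), cell cycle (0.0818), Wnt, BMP and Hedgehog targets (0.547) and housekeeping genes (0.176). The neural list had a median of -0.08 and a mean above 0, and the list of Wnt, BMP and Hedgehog targets a median of 0.02 with a mean and a camera test below 0. Liver and yolk sac genes had 6 of 19 members higher and 1 lower over both days, with a median of 0.35 (camera adjusted p = 0.00875, or adjusted p = 0.732 with an estimated correlation).

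Genes of cilia among the largest KGF differences led to a hypothesis that KGF may raise genes of the motile cilium as a set. A list of 42 cilium genes, written before their values were looked at, had 35 measured. Of these, 31 were above 0 with KGF, the median was 0.30, and none passed singly over all 10 arrays. Camera gave a p of 1.13e-14 at the preset correlation and of 0.0437 with an estimated correlation. The medians of the 4 later pairs lay between 0.07 and 0.61, and that of day 8 was -0.08. On the 8 later arrays 4 genes of the list passed (Dynlrb2, Capsl, Fam183b and Rsph4a), which are among the 65 changed there. Without these 4, 27 of 31 genes were above 0, with a median of 0.28, and camera gave a p of 3.9e-11 at the preset correlation and of 0.0518 with an estimated correlation. The call thus rests on the preset once they are left out. A larger share of ciliated cells and higher expression within them were not told apart. The general epithelium list had a median with KGF about as large, and camera compares a list with all other genes. A gain of epithelial genes in general was therefore not told apart either.

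The rises of gastric genes with DCI led to a second hypothesis, that DCI may raise genes of the stomach epithelium as a set. Of 17 stomach genes, listed before their values were looked at, 15 were measured and 13 were above 0, with a median of 0.22. Camera gave a p of 0.00141 at the preset correlation and 0.12 with an estimated correlation, so that the call rests on the preset. The 4 that passed were Cldn18, Muc5ac (1.67 ± 0.20), Ghrl (0.44 ± 0.13) and Vsig1 (0.44 ± 0.12). Muc5ac, 1 of the 15, is also on the airway list, and Cldn18 is known from lung epithelium too. Without Muc5ac, 12 of 14 genes were above 0, and camera gave a p of 0.00693 at the preset correlation and of 0.169 with an estimated correlation. The parietal cell proton pump genes Atp4a and Atp4b were at 0.22 ± 0.14 and 0.09 ± 0.10. With DCI the general epithelium list had a higher median than the stomach list, so a rise particular to stomach genes was not shown.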
